A study of Mus musculus with 16 samples.

How the data were processed

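Messenger RNA was measured in the livers of 16 mice in 4 groups of 4, with 1 library per animal. Livers were flash frozen, RNA was extracted with Trizol, and poly(A)-selected directional libraries were prepared, per the labels' protocols. TopHat2 version 2.1.1, featureCounts and the mouse genome build mm10 are named per the submitters' processing notes. The featureCounts version and options, the annotation release and the strand setting were not given in the sources used here. Because the strand setting is unknown, genes that overlap others on the opposite strand and genes with close copies have uncertain levels. The deposited values were raw read counts per gene with no normalization, as whole numbers with different library totals. All 16 columns were matched to a sample by its number, and no pair of libraries was identical.

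The table held 46078 genes, of which 22577 had no count in any library. A symbol was found for 45143 identifiers and a position for 45229 in GENCODE M21 (GRCm38). Identifiers without a symbol held 0.0335% to 0.0509% of each library's counts, and 56 symbols shared by several identifiers were kept as identifiers. The 37 mitochondrial genes in the table were all listed at 0. Library totals ranged from 12.144 to 18.755 M counts, with a mean of 15.331 M. The replicate correlations of log2 CPM across genes were 0.975 to 0.986 in saline, 0.972 to 0.983 in calorie restriction, 0.954 to 0.978 in Semaglutide and 0.946 to 0.973 in Dicretin. Genes are not independent replicates, and these correlations only describe the libraries.

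Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low counts were removed with filterByExpr on the 4 groups at its defaults, which left 12910 genes, and libraries were scaled with TMM factors. A single model with 1 mean per group was fitted to all 16 libraries with glmQLFit (robust), and each of the 6 contrasts was tested with glmQLFTest. The common biological coefficient of variation was 0.24. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, without adjustment across comparisons. The SE of a log2 fold change was its absolute value divided by the square root of F. CPM were computed with the TMM-scaled totals, and log2 CPM for principal components used a prior count of 2. Where a group had no counts, the fold was computed against a floor of 3 counts over the group and given as at least that value. Floors cover counting error only, and animals add to it. No covariate was used because the labels give no batch, sex or pairing.

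Gene lists were written from general knowledge of liver biology, and 38 of them with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation of 0.01) on the edgeR log2 values, with Benjamini-Hochberg adjustment over all lists and comparisons together. Some lists share members, so their calls are not separate results. The cyclic AMP and gluconeogenesis lists share Pck1, G6pc, Ppargc1a and Tat. Periportal genes share Cps1 and Arg1, among others, with the urea cycle, and Pck1 and Sds with gluconeogenesis. Pericentral genes share Cyp2c37 and Cyp2c50 with the CAR and PXR targets. A further list of genes served only for naming and was not tested as a set. Member counts are given over all genes and adjusted over the list alone. Camera with an estimated correlation is given beside each list, because with 4 libraries per group the preset value can understate the correlation between members. Named genes followed a rule with 3 parts. The first part took the 6 largest increases and the 6 largest decreases of each comparison among genes that passed, with a mean of at least 2 CPM in the higher group and no overlap between groups. It left out predicted genes, unnamed identifiers and antigen receptor segments. The second took up to 4 members with the smallest p from each list described, and the third was a fixed panel of 23 receptors, hormones and metabolic genes. A gene named in one comparison could be given in others. Some genes that the rule picks are not reported here. Which list members were used as examples within the rule was chosen with the results in view, leave-one-out values included.

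The samples, comparisons, tests, gene lists, naming rule and all alternatives except those named as added were chosen before the data were examined. The alternatives were DESeq2 1.42.0 size factors, upper quartile factors, the DESeq2 Wald test, limma-voom, no low-count filter, a filter of 1 CPM in at least 4 libraries, the 20 most abundant genes left out, only the 2 groups compared, each library left out in turn, fry in place of camera, and the shared group divided between the comparisons for shared calls. A correction for gene length was added after the data had been seen, in which the loess trend (span 0.5) of each library's log2 deviation on exon length was removed as an offset. Leaving out Semaglutide 11 and Dicretin 14 together was also added then. Lengths were known for 99.73% of the tested genes. All 35 ways to split 8 libraries into groups of 4 were counted for each comparison. Scripts ran on Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

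The test was checked on simulated counts for each comparison, with 200 genes changed among 12708 to 12728 tested. For Dicretin against saline, 53% of the 2-fold and 88% of the 4-fold changes were recovered, with 9 false calls. For Semaglutide against saline these were 49%, 94% and 4, for calorie restriction against saline 48%, 85% and 5, for Dicretin against calorie restriction 53%, 83% and 5, for Semaglutide against calorie restriction 48%, 90% and 13, and for Dicretin against Semaglutide 50%, 84% and 2. False calls were 5.92%, 2.68%, 3.6%, 3.52%, 8.44% and 1.47% of all calls in that order. In 20 simulated data sets without any change, the mean number of calls per comparison was 0 to 0.15 and the highest 2. A simulated set of 20 genes shifted by 0.5 on the log2 scale was called upward by camera in each comparison.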

Results

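Liver messenger RNA was profiled by strand-preserving, poly(A)-selected RNA sequencing in 16 obese C57BL/6 mice aged 22 weeks whose livers were steatotic. The libraries formed 4 groups of 4. Saline was the vehicle control, and the calorie-restricted group reached an equivalent weight loss through diet alone, per the series' design. Semaglutide is a peptide that activates the glucagon-like peptide-1 receptor (GLP1R), and Dicretin is a co-agonist of GLP1R and of the glucagon receptor (GCGR). Counts assigned to genes ranged from 12.144 to 18.755 M per library, with a mean of 14.852 ± 1.997 M in saline, 15.948 ± 2.221 M in calorie restriction, 15.259 ± 0.395 M in Semaglutide and 15.264 ± 2.066 M in Dicretin (SD, n = 4). Libraries are named below by group and by the number the submitters gave them. CPM values are means ± SD over the 4 libraries of a group, log2 fold changes are ± SE, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

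The first principal component, with 38.88% of the variance, placed the 4 Dicretin libraries between 66.57 and 76.84 and all other libraries between -30.4 and -11.67. The saline libraries lay apart from the rest on the component that held 10.38% of the variance, between -38.77 and -21.36. On the component with 14.78%, Semaglutide library 11 lay at 60.09 and its mates between -1.39 and 15.3, and the Dicretin libraries were spread from -39.25 (library 14) to 30.52. Albumin (Alb) took the largest share of counts in every library, with 5.92% ± 1.18 in Dicretin, 8.44% ± 0.50 in saline, 9.12% ± 0.41 in Semaglutide and 10.9% ± 1.22 in calorie restriction (SD, n = 4). The receptors that the drugs bind differed in level in the liver. Gcgr was measured at 225 ± 12.2 CPM in saline, 194 ± 14.5 CPM in calorie restriction, 241 ± 43.5 CPM in Semaglutide and 133 ± 26.6 CPM in Dicretin, while Glp1r received 3 counts over all 16 libraries and was not tested.

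**Figure D1:**
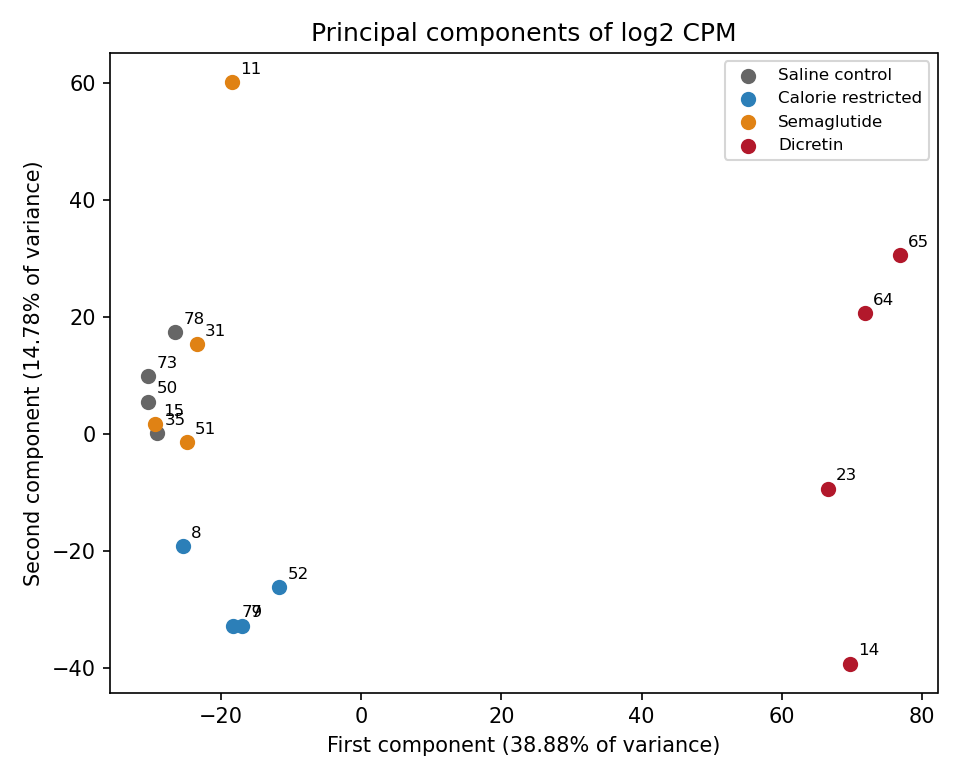
Positions of the 16 libraries on the first and second principal components of log2 CPM of the 12910 tested genes, coloured by group and labelled with the library number. The Dicretin libraries lie at 66.57 or above on the horizontal axis (38.88% of the variance), and Semaglutide 11 lies at 60.09 on the vertical axis (14.78%).

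Dicretin was compared with saline to ask what the co-agonist changed in the steatotic liver. In Dicretin livers, 15 of 19 genes that respond to cyclic AMP, the second messenger of the glucagon receptor, rose, and the list passed camera with an estimated correlation (adjusted p = 0.0364). By camera with the preset correlation, gluconeogenesis (10 of 17 rose), the urea cycle (7 of 9) and periportal hepatocyte genes (12 of 20) were higher. Bile acid synthesis and transport (15 of 24 fell), peroxisomal fatty acid oxidation (15 of 19) and pericentral hepatocyte genes (12 of 20) were lower. These 6 calls were lost with an estimated correlation, where adjusted p ranged from 0.102 to 0.288. Of 12910 genes tested, 4734 passed the adjusted p threshold of 0.05, with 2255 higher and 2479 lower in Dicretin, and 738 and 1321 of these differed by at least 2-fold.

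Among the cyclic AMP-responsive genes, 15 of 19 tested members rose (17 adjusted over the list alone), with a median log2 fold change of 2.83 (camera adjusted p = 1.47e-11, adjusted p = 0.0364 with an estimated correlation). Within it Ppargc1a, a coactivator of gluconeogenic transcription, rose by 2.83 ± 0.16, the transcription factor Crem by 3.56 ± 0.21, the nuclear receptor Nr4a1 by 4.24 ± 0.27 and the insulin-like growth factor binding protein Igfbp1 by 5.31 ± 0.39. Of the gluconeogenic genes, 10 rose and 3 fell of 17 tested members (10 and 3 adjusted over the list alone) (camera adjusted p = 0.00446, adjusted p = 0.111 with an estimated correlation). Tat, which starts tyrosine breakdown, rose by 3.09 ± 0.26, the aspartate aminotransferase Got1 by 3.30 ± 0.29, Pck1 by 1.57 ± 0.22 and the glucose-6-phosphatase gene G6pc by 1.70 ± 0.27, whereas the mitochondrial dicarboxylate carrier Slc25a10 had a log2 fold change of -1.43 ± 0.14. In the urea cycle, 7 rose and 1 fell of 9 tested members (7 and 2 adjusted over the list alone) (camera adjusted p = 0.000208, adjusted p = 0.137 with an estimated correlation). The ornithine carrier Slc25a15 rose from 186 ± 21.2 to 1223 ± 101 CPM, and Cps1, which commits ammonia to the cycle, from 2003 ± 379 to 5858 ± 595 CPM. The largest adjusted p among these genes was 9.65e-05.

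Among genes of the integrated stress and unfolded protein responses, 16 rose and 1 fell of 23 tested members (16 and 2 adjusted over the list alone) (camera adjusted p = 1.39e-05, adjusted p = 0.119 with an estimated correlation). The asparagine synthetase Asns rose by 6.31 ± 0.42, with Dicretin library 64 at 25.75 CPM and its mates at 17.73 to 18.88 CPM, and the transcription factors Atf5 and Atf4 by 1.99 ± 0.21 and 1.41 ± 0.15. Amino acid catabolism as a list did not pass (camera adjusted p = 0.0816, adjusted p = 0.796 with an estimated correlation), although 15 rose and 5 fell of 37 tested members (15 and 5 adjusted over the list alone), with the lysine-degrading Aass up by 2.42 ± 0.16 and the glyoxylate-handling Agxt at 1800.0 ± 579 against 226 ± 62 CPM. The list passed without Dicretin library 14 (adjusted p = 0.0055) or saline library 78 (adjusted p = 0.0439), and fry called it (adjusted p = 0.0404). Among receptor and hormone genes, the activin-binding follistatin gene Fst rose from 1.39 ± 0.48 to 69.5 ± 31.5 CPM, the leptin receptor Lepr from 2.36 ± 1.1 to 288 ± 29.1 CPM, and Fgf21 from 3.61 ± 2.3 to 22.6 ± 12.8 CPM (largest adjusted p 0.00385). Gdf15 passed the test (17.1 ± 6.71 against 7.02 ± 3.66 CPM, adjusted p = 0.0288), but not without Dicretin library 64 or 65 or saline library 50 or 78, where adjusted p was 0.0546, 0.091, 0.0843 and 0.0802, nor without the count filter (adjusted p = 0.0883).

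In periportal hepatocyte genes, 12 rose and 2 fell of 20 tested members (14 and 2 adjusted over the list alone) (camera adjusted p = 1e-04, adjusted p = 0.274 with an estimated correlation). The phospholyase gene Etnppl rose by 3.69 ± 0.23 and the serine dehydratase gene Sds by 2.48 ± 0.29. In pericentral genes, 2 rose and 12 fell of 20 tested members (2 and 13 adjusted over the list alone) (camera adjusted p = 0.001, adjusted p = 0.288 with an estimated correlation). The glutamine synthetase Glul stood at 342 ± 92.9 against 1611 ± 237 CPM and Cyp1a2 at 59.8 ± 20.6 against 270.3 ± 48.6 CPM. Among targets of the xenobiotic receptors CAR and PXR, 1 rose and 11 fell of 19 tested members (1 and 11 adjusted over the list alone) (camera adjusted p = 0.00348, adjusted p = 0.279 with an estimated correlation). Cyp2c50, Cyp2c54 and Cyp2c37 had log2 fold changes of -4.67 ± 0.36, -4.50 ± 0.47 and -3.66 ± 0.48. Their levels are uncertain because reads of this gene family can be split among close copies.

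In bile acid synthesis and transport, 1 rose and 15 fell of 24 tested members (1 and 16 adjusted over the list alone) (camera adjusted p = 0.000216, adjusted p = 0.102 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 119.9 ± 25.2 to 4.49 ± 4.92 CPM, the sterol 12-alpha-hydroxylase Cyp8b1 from 352 ± 123 to 38 ± 23.7 CPM, and the transporters Abcc3 and Slco1a1 had log2 fold changes of -2.54 ± 0.17 and -3.56 ± 0.41 (largest adjusted p 0.000134). Saline library 78 was at 168.8 CPM for Cyp8b1 and its mates at 396.8 to 434 CPM. In peroxisomal fatty acid oxidation, 15 of 19 tested members fell (15 adjusted over the list alone) (camera adjusted p = 3.49e-05, adjusted p = 0.266 with an estimated correlation). Triglyceride storage and lipid droplet genes did not pass as a list (camera adjusted p = 0.125, adjusted p = 0.668 with an estimated correlation), while fry called them (adjusted p = 0.000666) and 5 rose and 9 fell of 25 tested members (6 and 10 adjusted over the list alone). Within it Pparg, which drives lipid storage, fell from 33.7 ± 7.68 to 2.34 ± 0.199 CPM, and the droplet proteins Cidea and Cidec had log2 fold changes of -6.40 ± 0.61 and -2.56 ± 0.48. In de novo lipogenesis, 2 rose and 9 fell of 22 tested members (2 and 9 adjusted over the list alone) (camera adjusted p = 0.0181, adjusted p = 0.717 with an estimated correlation). Srebf1 stood at 56.5 ± 36.5 against 319.6 ± 24.5 CPM. The lipogenic genes Fasn and Scd1 did not pass and varied widely. They stood at 150.2 ± 249 against 236 ± 126 CPM and 2373 ± 3537 against 4960.0 ± 2729 CPM. Without Dicretin library 14 both passed, with log2 fold changes of -3.16 for Fasn (adjusted p = 0.00249) and -2.97 for Scd1 (adjusted p = 0.0143).

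The largest fitted increases among genes with separate groups were in transcripts nearly absent from saline liver. Wnt10a (chromosome 1, 74791516 to 74804179 in GRCm38), a secreted Wnt ligand, had no counts in saline and 17.4 ± 1.48 CPM in Dicretin, at least 359-fold higher. The renin gene Ren1 was at 14.5 ± 5.79 CPM, at least 299-fold higher, the thyroglobulin gene Tg at 8.69 ± 4.3 CPM, at least 179-fold higher, the protease Pappa2 at 6.05 ± 5.26 CPM, at least 125-fold higher, and the kinase Stk33 at 3.67 ± 2.33 CPM, at least 75.6-fold higher. The secreted hyaluronan-binding Tnfaip6 stood at 4.43 ± 0.383 CPM in Dicretin and 0.0145 ± 0.0291 CPM in saline. Rgs16, a regulator of G protein signalling (chromosome 1, 153740349 to 153745468), fell from 216 ± 73.8 to 0.25 ± 0.114 CPM, the thymocyte signalling gene Themis from 33.9 ± 8.88 to 0.123 ± 0.076 CPM, and the complement factor D gene Cfd from 29.9 ± 14.9 to 0.123 ± 0.193 CPM. A4gnt, with 2.1 ± 1.26 CPM in saline and no counts in Dicretin, was at least 42.6-fold lower, and Clec2h and the pseudogene Mup-ps14 had 0.0134 ± 0.0268 and 0.0158 ± 0.0317 CPM in Dicretin against 8.07 ± 5.86 and 2.38 ± 0.696 CPM. Pappa2 was at 13.87 CPM in Dicretin library 14 and at 2.599 to 4.268 CPM in its mates, and without that library the bound was 71.1-fold. Clec2h was at 16.79 CPM in saline library 78 and at 4.159 to 5.92 CPM in its mates, and without it the log2 fold change was -7.72 (adjusted p = 5.99e-07). Of the 38 lists, 17 passed camera with the preset correlation, 7 upward and 10 downward, and the cyclic AMP list alone also passed with an estimated correlation. The call of de novo lipogenesis was lost without Dicretin library 64 (adjusted p = 0.0554) or 65 (adjusted p = 0.0587).

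**Figure D2:**
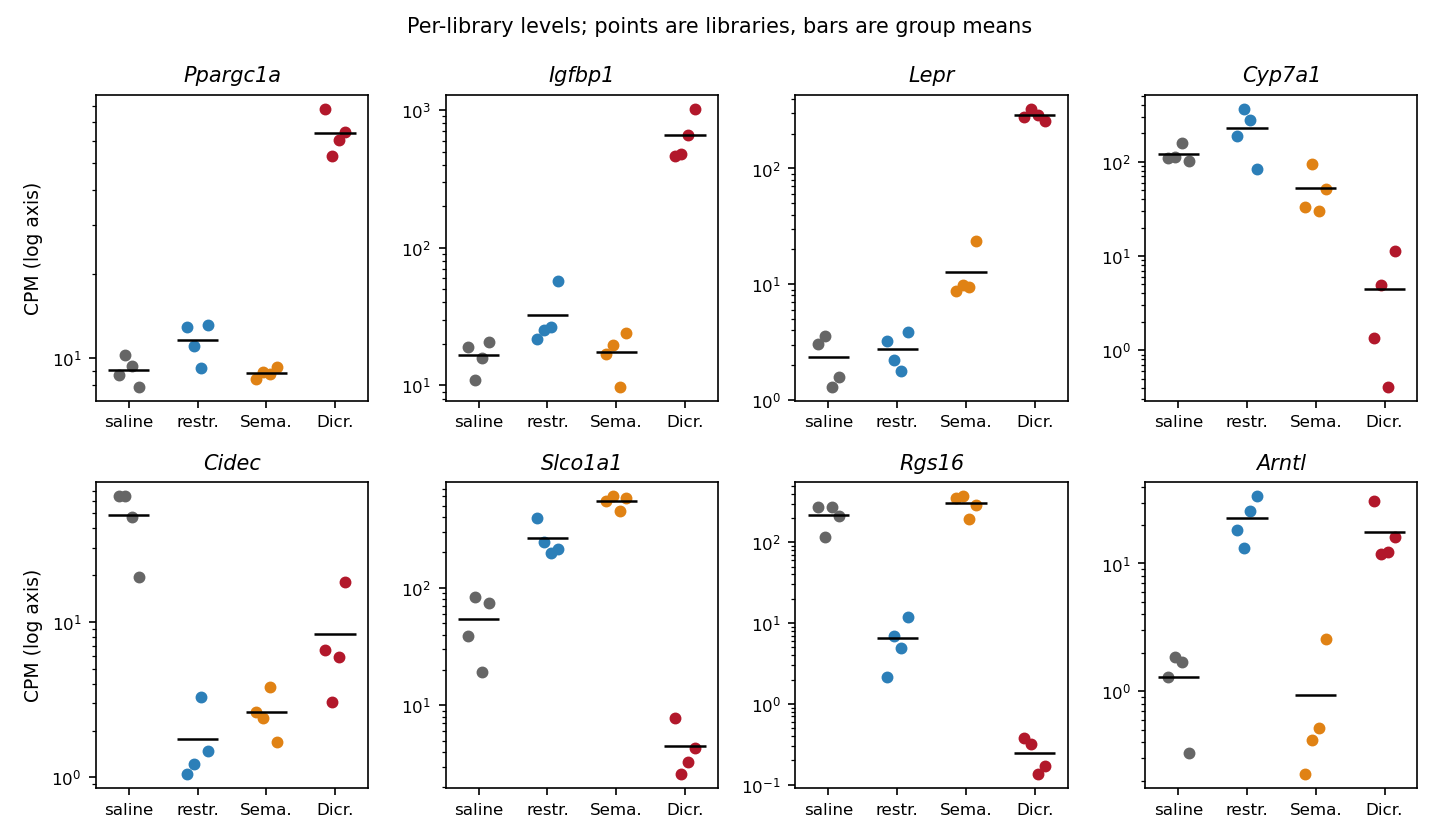
CPM of 8 named genes in each of the 16 libraries on a log axis, with a horizontal bar at each group's mean. Igfbp1 lay at 655 ± 259.5 CPM in Dicretin and 16.6 ± 4.26 CPM in saline, and Cidec at 1.76 ± 1.04 CPM in calorie restriction and 49.1 ± 21.3 CPM in saline (mean ± SD).

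Semaglutide was compared with saline to ask what GLP1R agonism alone, with its weight loss, changed in the liver. By camera with the preset correlation, the lists of lipid droplets (10 of 25 members fell), peroxisomal fatty acid oxidation (7 of 19) and female-biased hepatocyte genes (4 of 11) were lower, and male-biased hepatocyte genes (7 of 20 rose) were higher. No list passed with an estimated correlation, where adjusted p ranged from 0.0878 to 0.204 for these lists. In all, 539 of 12910 genes passed, 201 higher and 338 lower, with 73 and 217 of them differing by at least 2-fold.

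In triglyceride storage and lipid droplets, 10 of 25 tested members fell (10 adjusted over the list alone) (camera adjusted p = 3.41e-08, adjusted p = 0.0878 with an estimated correlation). Cidea fell from 7.5 ± 2.35 to 0.0857 ± 0.0636 CPM, Cidec from 49.1 ± 21.3 to 2.64 ± 0.885 CPM, the monoacylglycerol acyltransferase Mogat1 from 7.5 ± 2.67 to 1.15 ± 0.405 CPM and Pparg from 33.7 ± 7.68 to 8.43 ± 2.02 CPM. The fatty acid transporter Cd36 had a log2 fold change of -2.25 ± 0.34 and the droplet coat protein Plin2 one of -1.35 ± 0.26 (largest adjusted p of these genes 0.00543). In peroxisomal fatty acid oxidation, 7 of 19 tested members fell (11 adjusted over the list alone) (camera adjusted p = 1.41e-06, adjusted p = 0.199 with an estimated correlation). Among targets of the fatty acid sensor PPAR alpha, 6 of 22 tested members fell (7 adjusted over the list alone) (camera adjusted p = 0.000142, adjusted p = 0.411 with an estimated correlation). In gluconeogenesis, 4 of 17 tested members fell (6 adjusted over the list alone) (camera adjusted p = 0.00037, adjusted p = 0.0791 with an estimated correlation). G6pc stood at 77.8 ± 28.3 against 261 ± 69.6 CPM. Pck1, at 1810.0 ± 558 against 2027 ± 615 CPM, did not pass.

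In male-biased hepatocyte genes, 7 rose and 0 fell of 20 tested members (13 and 1 adjusted over the list alone) (camera adjusted p = 8.49e-09, adjusted p = 0.204 with an estimated correlation). The organic anion transporter Slco1a1 rose from 53.9 ± 29.8 to 544 ± 67.8 CPM, the oxysterol hydroxylase Cyp7b1 from 102 ± 28.1 to 246 ± 17.9 CPM, and the steroid dehydrogenase Hsd3b5 and the major urinary protein Mup11 had log2 fold changes of 6.12 ± 0.90 and 2.66 ± 0.50. In female-biased genes, 4 of 11 tested members fell (6 adjusted over the list alone) (camera adjusted p = 0.000113, adjusted p = 0.11 with an estimated correlation), including the flavin monooxygenase Fmo2 (-1.41 ± 0.26 on the log2 scale). Serpina1e had a log2 fold change of 3.20 ± 0.65. Hsd3b5, Mup11 and Serpina1e belong to families of near-identical genes, so their levels are uncertain. The sex of the animals was not given in the sources used here. Among targets of NRF2, a transcription factor of the oxidative stress response, 0 rose and 5 fell of 17 tested members (1 and 7 adjusted over the list alone) (camera adjusted p = 0.00037, adjusted p = 0.239 with an estimated correlation), led by the glutathione transferase Gstm2 at -1.82 ± 0.22. In the integrated stress and unfolded protein response list, 5 rose and 0 fell of 23 tested members (12 and 2 adjusted over the list alone) (camera adjusted p = 0.000197, adjusted p = 0.204 with an estimated correlation).

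The metal-binding Mt2 (chromosome 8, 94172664 to 94173568) fell from 96.3 ± 22.2 to 5.25 ± 2.43 CPM, Themis from 33.9 ± 8.88 to 0.518 ± 0.205 CPM and Cfd from 29.9 ± 14.9 to 0.26 ± 0.472 CPM, and A4gnt stood at 0.0162 ± 0.0324 against 2.1 ± 1.26 CPM. The kinase Wnk4 rose by 2.93 ± 0.38, the peptide hormone gene Enho by 2.60 ± 0.40, Lepr by 2.42 ± 0.34 and Igfbp2 by 1.79 ± 0.31. Cyp8b1 fell from 352 ± 123 to 39.7 ± 18.1 CPM (largest adjusted p of these genes 0.00291). Enho was at 58.35 CPM in Semaglutide library 11 and 32.18 to 34.67 CPM in its mates, Lepr at 23.41 CPM in library 51 and 8.7 to 9.803 CPM in its mates, and Cyp8b1 at 168.8 CPM in saline library 78 and 396.8 to 434 CPM in its mates. With these libraries left out in turn, the log2 fold changes were 2.36 (adjusted p = 0.00665), 1.96 (adjusted p = 0.00114) and -3.38 (adjusted p = 0.000887). Of the 38 lists, 19 passed camera, 3 upward and 16 downward, and none did with an estimated correlation, while 11 passed fry. In oxidative phosphorylation, none of 39 tested members passed the edgeR test or the test adjusted over the list alone, 4 higher and 1 lower members had an unadjusted p under 0.05, and DESeq2 called 0 higher and 0 lower, while the list was higher (camera adjusted p = 0.0128, adjusted p = 0.825 with an estimated correlation), a call kept with the length trend removed (adjusted p = 0.0402) and lost with fry (adjusted p = 0.518) or without Semaglutide library 11 (adjusted p = 0.76, in the opposite direction) or saline library 35 (adjusted p = 0.0955). The 539 calls became 256 without saline library 35, 268 without 50 and 300 without 73, and DESeq2 called 943.

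Calorie restriction was compared with saline to ask what weight loss without a drug changed. By camera with the preset correlation, the lists of lipid droplets (11 of 25 members fell), acute-phase proteins (6 of 26), chemokines, cytokines and adhesion molecules (4 of 18) and resident macrophages (2 of 15) were lower. Those of the stress and unfolded protein responses (10 of 23 rose) and of cholesterol synthesis and uptake (3 of 24) were higher. No list passed with an estimated correlation, where adjusted p ranged from 0.11 to 0.668 for these lists, and fry did not call those of macrophages and cholesterol. Among 19 clock genes 5 rose and 5 fell. Of 12910 genes, 972 passed, 442 higher and 530 lower, and 153 and 295 of them differed by at least 2-fold.

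In triglyceride storage and lipid droplets, 1 rose and 11 fell of 25 tested members (2 and 13 adjusted over the list alone) (camera adjusted p = 2.07e-06, adjusted p = 0.11 with an estimated correlation). Cidec fell from 49.1 ± 21.3 to 1.76 ± 1.04 CPM, Cidea from 7.5 ± 2.35 to 0.175 ± 0.177 CPM and the lipase Lipe from 28 ± 4.66 to 7.42 ± 0.486 CPM (largest adjusted p 5.44e-05). In the stress and unfolded protein responses, 10 rose and 2 fell of 23 tested members (11 and 2 adjusted over the list alone) (camera adjusted p = 0.00143, adjusted p = 0.274 with an estimated correlation). The endoplasmic reticulum chaperones Dnajb11, Hyou1 and Hspa5 rose by 1.25 ± 0.14, 2.15 ± 0.30 and 1.51 ± 0.25. In cholesterol biosynthesis and uptake, 3 of 24 tested members rose (5 adjusted over the list alone) (camera adjusted p = 0.000197, adjusted p = 0.668 with an estimated correlation). Restricted library 79 was the highest of its group, with a list mean of 7.22 log2 CPM against 5.51 to 6.39 in its mates and 5.39 to 5.9 in saline. Without it camera gave adjusted p = 0.0243, and the list did not pass fry with it (adjusted p = 0.182). Insig1, a regulator of sterol synthesis, rose by 1.33 ± 0.25.

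Among acute-phase proteins, 1 rose and 6 fell of 26 tested members (1 and 7 adjusted over the list alone) (camera adjusted p = 0.00236, adjusted p = 0.495 with an estimated correlation). Orm2 had a log2 fold change of -2.17 ± 0.30 and the interleukin-1 receptor antagonist Il1rn one of -2.76 ± 0.32. In the list of chemokines, cytokines and adhesion molecules, 4 of 18 tested members fell (9 adjusted over the list alone) (camera adjusted p = 1.95e-05, adjusted p = 0.279 with an estimated correlation). In resident Kupffer cell markers, 2 of 15 tested members fell (6 adjusted over the list alone), with a median of -1.06 (camera adjusted p = 0.000195, adjusted p = 0.601 with an estimated correlation). Fry did not call this list (adjusted p = 0.0911), and 3 of 4 restricted libraries lay below every saline library. Lists of other cells were also lower by camera. In monocyte-derived and lipid-associated macrophage markers, none of 19 tested members passed the edgeR test or the test adjusted over the list alone, 0 higher and 8 lower members had an unadjusted p under 0.05, and DESeq2 called 0 higher and 0 lower (camera adjusted p = 0.00247, adjusted p = 0.414 with an estimated correlation). In stellate cell and extracellular matrix genes, none of 29 tested members passed the edgeR test or the test adjusted over the list alone, 0 higher and 9 lower members had an unadjusted p under 0.05, and DESeq2 called 0 higher and 0 lower (camera adjusted p = 0.0372, adjusted p = 0.748 with an estimated correlation), a call lost with fry (adjusted p = 0.278) and without restricted library 8 or 79 or saline library 35 or 50 (adjusted p from 0.0735 to 0.187). In erythroid markers, none of 7 tested members passed the edgeR test (0 higher and 3 lower adjusted over the list alone), 0 higher and 3 lower members had an unadjusted p under 0.05, and DESeq2 called 0 higher and 2 lower (camera adjusted p = 0.0297, adjusted p = 0.495 with an estimated correlation), a call lost without restricted library 8 or 79 or saline library 35 or 73 (adjusted p from 0.0511 to 0.0662) and with the length trend removed (adjusted p = 0.102). Among clock genes, 5 rose and 5 fell of 19 tested members (5 and 8 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.499, adjusted p = 0.863 with an estimated correlation). The clock activator Arntl rose from 1.3 ± 0.687 to 22.8 ± 9 CPM and the repressor Cry1 from 10.6 ± 2.19 to 55.6 ± 11.3 CPM, while Dbp fell from 101 ± 8.67 to 9.87 ± 4.89 CPM and Nr1d1 from 32.4 ± 5.45 to 7.33 ± 0.758 CPM (largest adjusted p 0.000262).

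The metallothioneins Mt1 and Mt2 were among the 6 largest decreases named, with Mt1 (chromosome 8, 94179082 to 94180327) at 4.31 ± 1.87 against 187 ± 30.6 CPM and Mt2 at 1.54 ± 0.876 against 96.3 ± 22.2 CPM. Cfd had a log2 fold change of -5.84 ± 0.83, and A4gnt stood at 0.0337 ± 0.0396 against 2.1 ± 1.26 CPM. The vasopressin receptor Avpr1a rose by 3.32 ± 0.30, the fatty acid elongase Elovl3 by 2.83 ± 0.62, Fam222a by 3.65 ± 0.46, the homeobox gene Pitx3 by 3.58 ± 0.72 and Hsd3b5 by 4.29 ± 0.84, the last of which did not pass when only these groups were fitted (adjusted p = 0.0502). Pitx3 was at 6.947 CPM in restricted library 79 and at 1.375 to 2.219 CPM in its mates, and without that library it rose by 2.77 (adjusted p = 0.0288). Mup18, of the major urinary protein family whose copies share reads, stood at 0.54 ± 0.27 against 19.5 ± 30.3 CPM (adjusted p = 0.0206), a call lost without calorie-restricted library 7, 52 or 79 or saline library 50, with adjusted p from 0.0607 to 0.0783, and without the count filter (adjusted p = 0.0592), in a fit of these groups alone (0.0651) or with limma-voom (0.159). Of the 38 lists, 15 passed camera, 3 upward and 12 downward, none passed with an estimated correlation, and 9 passed fry, while 9 passed camera without calorie-restricted library 8. The 972 calls became 502 without calorie-restricted library 7, 526 without saline 35, 554 without saline 73 and 556 without saline 50. They rose to 2569 when only these groups were fitted, to 1880 without Semaglutide 11 and Dicretin 14, and to 1465 with DESeq2.

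**Figure D3:**
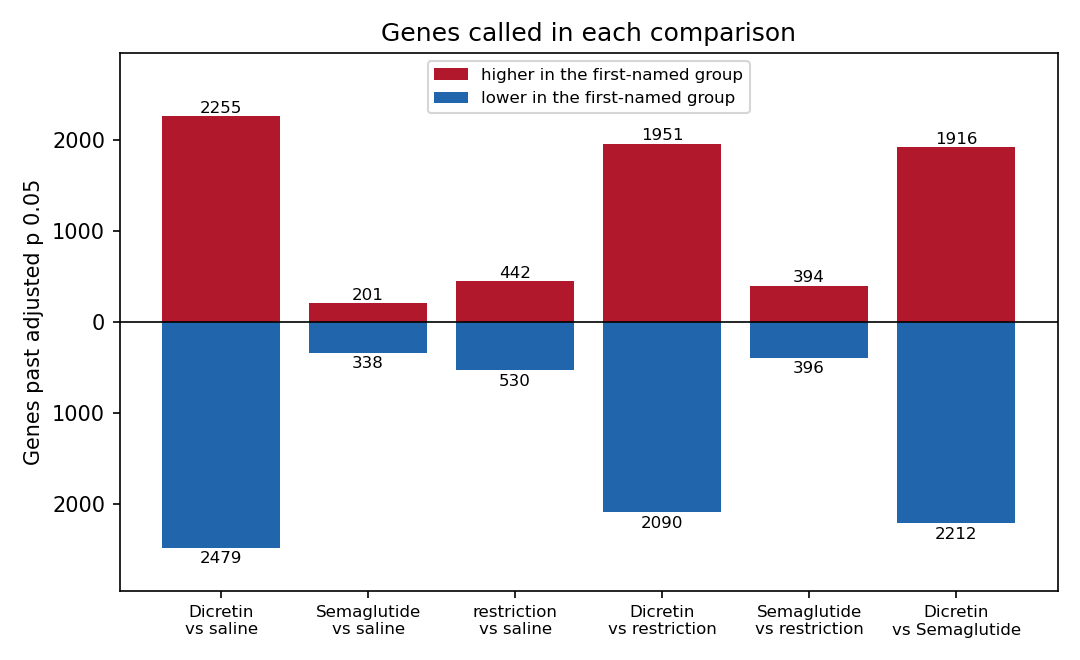
Genes that passed the adjusted p threshold of 0.05 in each of the 6 comparisons, with bars upward for genes higher in the first-named group and bars downward for genes lower in it. The Dicretin comparisons hold 4734, 4041 and 4128 calls and the other comparisons 539, 972 and 790.

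Dicretin was compared with calorie restriction to set the co-agonist beside weight loss of similar size by diet. Because feeding and sampling times were not given in the sources used here, differences that follow them cannot be told apart from drug effects. With Dicretin 17 of 19 cyclic AMP-responsive genes were higher, and the list passed camera with an estimated correlation (adjusted p = 0.0364). By camera with the preset correlation, gluconeogenesis (10 of 17 higher), the urea cycle (7 of 9), autophagy (10 of 22) and resident macrophage markers (9 of 15) were higher. Cholesterol synthesis and uptake (18 of 24 lower), bile acids (15 of 24), peroxisomal oxidation (11 of 19) and pericentral genes (12 of 20) were lower. These 8 calls were lost with an estimated correlation, where adjusted p ranged from 0.0892 to 0.668, and fry did not call the macrophage markers. Of 12910 genes, 4041 passed, 1951 higher and 2090 lower in Dicretin, with 728 and 1014 of them at least 2-fold apart.

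In the cyclic AMP list, 17 of 19 tested members rose (19 adjusted over the list alone) (camera adjusted p = 6.47e-12, adjusted p = 0.0364 with an estimated correlation). Nr4a1 rose by 4.90 ± 0.29 and Ppargc1a rose by 2.47 ± 0.16. In gluconeogenesis, 10 rose and 2 fell of 17 tested members (11 and 2 adjusted over the list alone) (camera adjusted p = 0.00152, adjusted p = 0.0948 with an estimated correlation). In the urea cycle 7 rose and 1 fell of 9 tested members (7 and 1 adjusted over the list alone) (camera adjusted p = 0.000862, adjusted p = 0.204 with an estimated correlation). Got1 had a log2 fold change of 3.12 ± 0.28 and the arginase gene Arg1 one of 1.65 ± 0.22. In cholesterol biosynthesis and uptake, 18 of 24 tested members fell (19 adjusted over the list alone), with a median of -1.73 (camera adjusted p = 3.19e-06, adjusted p = 0.543 with an estimated correlation). Hmgcs1 stood at 38.1 ± 9.24 CPM with Dicretin and 351 ± 289 CPM with restriction, and Insig1 at 78.8 ± 19.3 against 374 ± 108 CPM. Restricted library 79 had 783.9 CPM of Hmgcs1 and its mates 193.3 to 218.1 CPM, and without it the Hmgcs1 log2 fold change went from -3.20 ± 0.40 to -2.44 (adjusted p = 6.95e-07) and the list gave camera adjusted p = 2.8e-05. In bile acid synthesis and transport, 2 rose and 15 fell of 24 tested members (2 and 17 adjusted over the list alone) (camera adjusted p = 0.000119, adjusted p = 0.0892 with an estimated correlation). Cyp7a1 stood at 4.49 ± 4.92 against 228 ± 120.1 CPM. In peroxisomal fatty acid oxidation, 11 of 19 tested members fell (11 adjusted over the list alone) (camera adjusted p = 0.000922, adjusted p = 0.386 with an estimated correlation). In pericentral genes 2 rose and 12 fell of 20 tested members (3 and 12 adjusted over the list alone) (camera adjusted p = 0.000227, adjusted p = 0.266 with an estimated correlation), while in periportal genes 11 rose and 2 fell of 20 tested members (13 and 2 adjusted over the list alone) (camera adjusted p = 0.00037, adjusted p = 0.316 with an estimated correlation).

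In resident Kupffer cell markers, 9 of 15 tested members rose (9 adjusted over the list alone) (camera adjusted p = 0.00193, adjusted p = 0.668 with an estimated correlation). The scavenger receptor Cd163 stood at 11.7 ± 4.73 against 3.2 ± 1.65 CPM, and fry did not call the list (adjusted p = 0.0624). Its mean lay above every restricted library in 3 of 4 Dicretin libraries, with library 23 at 3.61 and restricted library 52 at 4.03 log2 CPM. List means were 3.61 to 4.9 log2 CPM with Dicretin, 2.48 to 4.03 with restriction and 3.76 to 4.44 in saline. Against saline, 0 members were higher and 1 lower with Dicretin at an unadjusted p under 0.05. The difference thus lay mainly in lower restricted levels, not in a clear rise above saline. In monocyte-derived and lipid-associated macrophage markers, 7 rose and 1 fell of 19 tested members (7 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0806, adjusted p = 0.668 with an estimated correlation) except without Dicretin library 14 (adjusted p = 0.0215), restricted library 52 (adjusted p = 0.0486) or Semaglutide 11 and Dicretin 14 together (adjusted p = 0.0242). In chemokines, cytokines and adhesion molecules, 5 of 18 tested members rose (5 adjusted over the list alone) (camera adjusted p = 0.0328, adjusted p = 0.668 with an estimated correlation), a call lost with fry (adjusted p = 0.0776), without Dicretin library 65 (adjusted p = 0.186) and with the length trend removed (adjusted p = 0.118). Means of this chemokine list were 1.39 to 2.56 log2 CPM with Dicretin, 0.81 to 1.5 with restriction and 2.06 to 2.27 in saline. Against saline, 2 of its members were higher and 5 lower with Dicretin at an unadjusted p under 0.05. In autophagy, 10 rose and 2 fell of 22 tested members (11 and 2 adjusted over the list alone) (camera adjusted p = 0.00652, adjusted p = 0.204 with an estimated correlation). List means were 6.24 to 6.44 log2 CPM with Dicretin, 5.84 to 6.1 with restriction and 6.17 to 6.25 in saline. The cargo receptor Sqstm1 rose by 1.17 ± 0.14. In amino acid transport, 6 rose and 2 fell of 14 tested members (7 and 2 adjusted over the list alone) (camera adjusted p = 0.00702, adjusted p = 0.279 with an estimated correlation). The heavy chain Slc3a2 rose by 2.06 ± 0.15. Among receptor and hormone genes, Lepr rose by 6.70 ± 0.38, Igfbp1 by 4.33 ± 0.37, Fgf21 by 3.11 ± 0.65 and Gdf15 by 2.28 ± 0.46, and Pparg was lower by a log2 fold change of -2.46 ± 0.24 (largest adjusted p 0.00181). Restricted library 79 was the highest of its group for Igfbp1 (57.05 against 21.78 to 26.48 CPM), Fgf21 (5.945 against 1.256 to 1.81 CPM) and Gdf15 (7.682 against 1.833 to 2.278 CPM). Without it these genes rose by 4.74 (adjusted p = 1.12e-07), 3.88 (adjusted p = 0.000435) and 3.004 (adjusted p = 6.61e-05). Cidec, at 8.42 ± 6.63 CPM with Dicretin and 1.76 ± 1.04 CPM with restriction, was higher with Dicretin (2.20 ± 0.53), while Cidea, at 0.073 ± 0.0662 and 0.175 ± 0.177 CPM, and Plin2, at 356 ± 133 and 438 ± 113 CPM, did not pass.

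With no counts in calorie restriction, Wnt10a was at least 374-fold, Ren1 at least 311-fold, Pappa2 at least 130-fold (74-fold without Dicretin library 14) and Stk33 at least 78.7-fold higher with Dicretin, and Tg stood at 8.69 ± 4.3 against 0.0146 ± 0.0292 CPM. The aldose reductase family member Akr1b7 rose from 0.0961 ± 0.112 to 35.2 ± 32.6 CPM. Slco1a1, Hsd3b5, Cyp2c54 and Cyp4a12a had log2 fold changes of -5.86 ± 0.45, -7.65 ± 1.11, -6.29 ± 0.51 and -5.85 ± 0.65, the last 3 of them in families whose copies share reads. Clec2h stood at 0.0134 ± 0.0268 against 2.75 ± 1.78 CPM. Of the 38 lists, 18 passed camera, 11 upward and 7 downward, and the cyclic AMP list alone also passed with an estimated correlation. No library, when left out, moved the 4041 calls by more than 1.5-fold.

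Semaglutide was compared with calorie restriction to set GLP1R agonism beside weight loss of similar size by diet. Feeding and sampling times were not given in the sources used here. Differences that follow those times therefore cannot be told apart from effects of the drug. By camera with the preset correlation, the lists of cholesterol synthesis and uptake (5 of 24 members lower), gluconeogenesis (3 of 17), the urea cycle (2 of 9) and one-carbon metabolism (3 of 19) were lower with Semaglutide, and male-biased (7 of 20 higher) and autophagy genes (4 of 22) were higher. No list passed with an estimated correlation, where adjusted p ranged from 0.0878 to 0.495 for these lists, and fry did not call the cholesterol list. Among 19 clock genes 7 were higher and 5 lower. Of 12910 genes, 790 passed, 394 higher and 396 lower, with 183 and 175 of them at least 2-fold apart.

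In cholesterol biosynthesis and uptake, 5 of 24 tested members fell (15 adjusted over the list alone), with a median of -1.06 (camera adjusted p = 1.19e-07, adjusted p = 0.495 with an estimated correlation). Fry did not call it (adjusted p = 0.0528), and 2 of 4 Semaglutide libraries lay below every restricted library. The transcription factor Srebf2, which drives these genes, stood at 23.6 ± 7.15 against 49.4 ± 15.8 CPM. Restricted library 79 was at 73.01 CPM for Srebf2 and its mates at 40.17 to 42.4 CPM, and without it the log2 fold change was -0.81 (adjusted p = 0.0354) and the list gave camera adjusted p = 4.12e-05. In gluconeogenesis, 3 of 17 tested members fell (5 adjusted over the list alone) (camera adjusted p = 0.000739, adjusted p = 0.0878 with an estimated correlation). G6pc stood at 77.8 ± 28.3 against 543 ± 149 CPM. In the urea cycle, 2 of 9 tested members fell (4 adjusted over the list alone) (camera adjusted p = 0.00698, adjusted p = 0.279 with an estimated correlation). Slc25a15 had a log2 fold change of -0.90 ± 0.14. In one-carbon and methionine metabolism, 3 of 19 tested members fell (8 adjusted over the list alone) (camera adjusted p = 0.00108, adjusted p = 0.11 with an estimated correlation). The betaine methyltransferase Bhmt had a log2 fold change of -2.14 ± 0.41. In the cyclic AMP list, 4 of 19 tested members fell (6 adjusted over the list alone) (camera adjusted p = 0.00317, adjusted p = 0.289 with an estimated correlation). In autophagy, 4 rose and 0 fell of 22 tested members (6 and 1 adjusted over the list alone) (camera adjusted p = 0.0145, adjusted p = 0.266 with an estimated correlation). List means were 6.18 to 6.25 log2 CPM with Semaglutide, 5.84 to 6.1 with restriction and 6.17 to 6.25 in saline. The difference thus lay in lower restricted levels, not in a rise above saline. Map1lc3b rose by 0.84 ± 0.16.

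In male-biased hepatocyte genes, 7 rose and 1 fell of 20 tested members (16 and 2 adjusted over the list alone) (camera adjusted p = 1.41e-06, adjusted p = 0.274 with an estimated correlation). In female-biased genes 2 of 11 tested members fell (3 adjusted over the list alone) (camera adjusted p = 0.022, adjusted p = 0.366 with an estimated correlation). Mup20 stood at 9775 ± 4083 against 2098 ± 765 CPM. Among clock genes, 7 rose and 5 fell of 19 tested members (8 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.574, adjusted p = 0.879 with an estimated correlation). Arntl and Cry1 had log2 fold changes of -4.56 ± 0.58 and -2.83 ± 0.23, and Nr1d1, Dbp and Bhlhe41 ones of 3.25 ± 0.26, 3.77 ± 0.38 and 3.35 ± 0.45. Rgs16 was at 302 ± 80.4 CPM with Semaglutide, 6.45 ± 4.11 CPM with restriction and 216.5 ± 73.85 CPM in saline. The acetyltransferase-like Nat8f5 and the tubulin Tubb2a had log2 fold changes of -4.09 ± 0.66 and -3.48 ± 0.37, and Cyp8b1 one of -2.97 ± 0.50 (largest adjusted p of the genes in this paragraph so far 0.00233). Mup15, Mup17 and Mup18, whose levels are uncertain because their copies share reads, stood at 354 ± 177, 594 ± 192 and 16.8 ± 6.65 CPM with Semaglutide against 7.71 ± 6.67, 21.4 ± 22.2 and 0.54 ± 0.27 CPM. Mup17 was at 54.38 CPM in restricted library 8 and at 6.657 to 13.56 CPM in its mates. Their calls (largest adjusted p 0.0325) were lost without calorie-restricted library 7, 52 or 79 (adjusted p from 0.0538 to 0.101), those of Mup15 and Mup18 also without restricted library 8 or Semaglutide 11 or 31, and that of Mup15 without Semaglutide 15 (adjusted p from 0.0524 to 0.0854). Without the count filter Mup15 and Mup18 did not pass either (adjusted p = 0.0651 and 0.0773), nor did Mup18 with limma-voom (0.0836). Pitx3, at 0.308 ± 0.232 against 3.02 ± 2.65 CPM, passed (adjusted p = 0.0102) but not without restricted library 79, which was at 6.947 CPM with its mates at 1.375 to 2.219 CPM (adjusted p = 0.0536). Of the 38 lists, 14 passed camera, 3 upward and 11 downward, none passed with an estimated correlation, and 8 passed fry. The 790 calls became 445 without calorie-restricted library 7, 460 without 52, 503 without Semaglutide 11 and 493 without Semaglutide 31, and DESeq2 called 1266.

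Dicretin was compared with Semaglutide because the co-agonist activates GCGR as well as GLP1R. The drugs are different peptides, and doses and treatment length were not given in the sources used here. Differences between them therefore cannot be assigned to GCGR agonism alone. With Dicretin 16 of 19 cyclic AMP-responsive and 11 of 17 gluconeogenic genes were higher, and both lists passed camera with an estimated correlation (adjusted p = 0.0364). Both hold Pck1, G6pc, Ppargc1a and Tat, so they are not separate results. By camera with the preset correlation, the urea cycle (7 of 9 higher), one-carbon metabolism (12 of 19), amino acid catabolism (17 of 37) and periportal genes (13 of 20) were higher. Male-biased (14 of 20 lower), bile acid (14 of 24) and pericentral genes (11 of 20) were lower. These 7 calls were lost with an estimated correlation, where adjusted p ranged from 0.0791 to 0.668. Of 12910 genes, 4128 passed, 1916 higher and 2212 lower, with 787 and 1125 of them at least 2-fold apart.

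In the cyclic AMP list, 16 of 19 tested members rose (17 adjusted over the list alone), with a median of 2.86 (camera adjusted p = 1.4e-14, adjusted p = 0.0364 with an estimated correlation). In gluconeogenesis, 11 rose and 2 fell of 17 tested members (11 and 2 adjusted over the list alone) (camera adjusted p = 1.95e-05, adjusted p = 0.0364 with an estimated correlation). Gluconeogenesis list means were 8.93 to 9.14 log2 CPM with Dicretin, 7.65 to 7.74 with Semaglutide and 8.01 to 8.17 in saline. Part of this difference thus lay in Semaglutide levels below saline. Ppargc1a rose by 2.86 ± 0.16, Crem by 3.03 ± 0.20, G6pc by 3.44 ± 0.29 and Pck1 by 1.74 ± 0.22. In the urea cycle, 7 rose and 1 fell of 9 tested members (7 and 2 adjusted over the list alone) (camera adjusted p = 7.81e-05, adjusted p = 0.11 with an estimated correlation), in amino acid catabolism 17 rose and 5 fell of 37 tested members (18 and 5 adjusted over the list alone) (camera adjusted p = 0.00158, adjusted p = 0.668 with an estimated correlation). In one-carbon metabolism 12 rose and 1 fell of 19 tested members (12 and 2 adjusted over the list alone) (camera adjusted p = 0.00152, adjusted p = 0.11 with an estimated correlation). The nicotinamide methyltransferase Nnmt rose from 76.5 ± 41 to 1650.0 ± 523 CPM, Aass by 2.49 ± 0.16 and Slc25a15 by 2.67 ± 0.14. Nnmt was at 137.7 CPM in Semaglutide library 11 and at 52.47 to 62.54 CPM in its mates, and without that library it rose by 4.88 (adjusted p = 7.97e-09). In periportal genes, 13 rose and 2 fell of 20 tested members (13 and 2 adjusted over the list alone) (camera adjusted p = 4.84e-05, adjusted p = 0.268 with an estimated correlation). Etnppl stood at 1496 ± 404 against 64.7 ± 10.7 CPM. The largest adjusted p among these genes was 1.08e-05.

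In male-biased hepatocyte genes, 14 of 20 tested members fell (18 adjusted over the list alone), with a median of -1.65 (camera adjusted p = 3.94e-08, adjusted p = 0.226 with an estimated correlation). Slco1a1 stood at 4.5 ± 2.29 against 544 ± 67.8 CPM, and Hsd3b5 had a log2 fold change of -9.48 ± 1.14, subject to its close copies. In bile acid synthesis and transport, 0 rose and 14 fell of 24 tested members (1 and 15 adjusted over the list alone) (camera adjusted p = 2.54e-05, adjusted p = 0.0791 with an estimated correlation). Cyp7a1 stood at 4.49 ± 4.92 against 52.2 ± 29.6 CPM, whereas Cyp8b1, at 38 ± 23.7 and 39.7 ± 18.1 CPM, did not pass. In pericentral genes, 5 rose and 11 fell of 20 tested members (6 and 11 adjusted over the list alone) (camera adjusted p = 0.0195, adjusted p = 0.533 with an estimated correlation). Gcgr itself was lower with Dicretin, at 133 ± 26.6 against 241 ± 43.5 CPM (adjusted p = 0.000336).

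Pappa2 and Stk33 had no counts with Semaglutide and were at least 119-fold and 72.5-fold higher with Dicretin, and the Pappa2 bound was 67.7-fold without Dicretin library 14. Wnt10a, Ren1 and the protease Tmprss7 stood at 0.0157 ± 0.0313, 0.0162 ± 0.0324 and 0.0187 ± 0.0375 CPM with Semaglutide against 17.4 ± 1.48, 14.5 ± 5.79 and 4.06 ± 1.8 CPM, and Akr1b7 rose by 7.25 ± 1.08. Rgs16 and Serpina4-ps1 had log2 fold changes of -10.13 ± 0.57 and -8.07 ± 1.33, and Clec2h stood at 0.0134 ± 0.0268 against 14.5 ± 3.77 CPM. Lmod2, a muscle actin-nucleating gene, had no counts with Dicretin and 3.02 ± 4.45 CPM with Semaglutide, at least 61.3-fold, most of it from library 15 at 9.67 CPM, without which the bound was 16.4-fold. Of the 38 lists, 11 passed camera, 8 upward and 3 downward, and the cyclic AMP and gluconeogenesis lists passed with an estimated correlation. The 4128 calls became 2658 when only these groups were fitted, and no single library moved them by more than 1.5-fold. Without Semaglutide 11 and Dicretin 14, 17 lists passed.

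**Figure D4:**
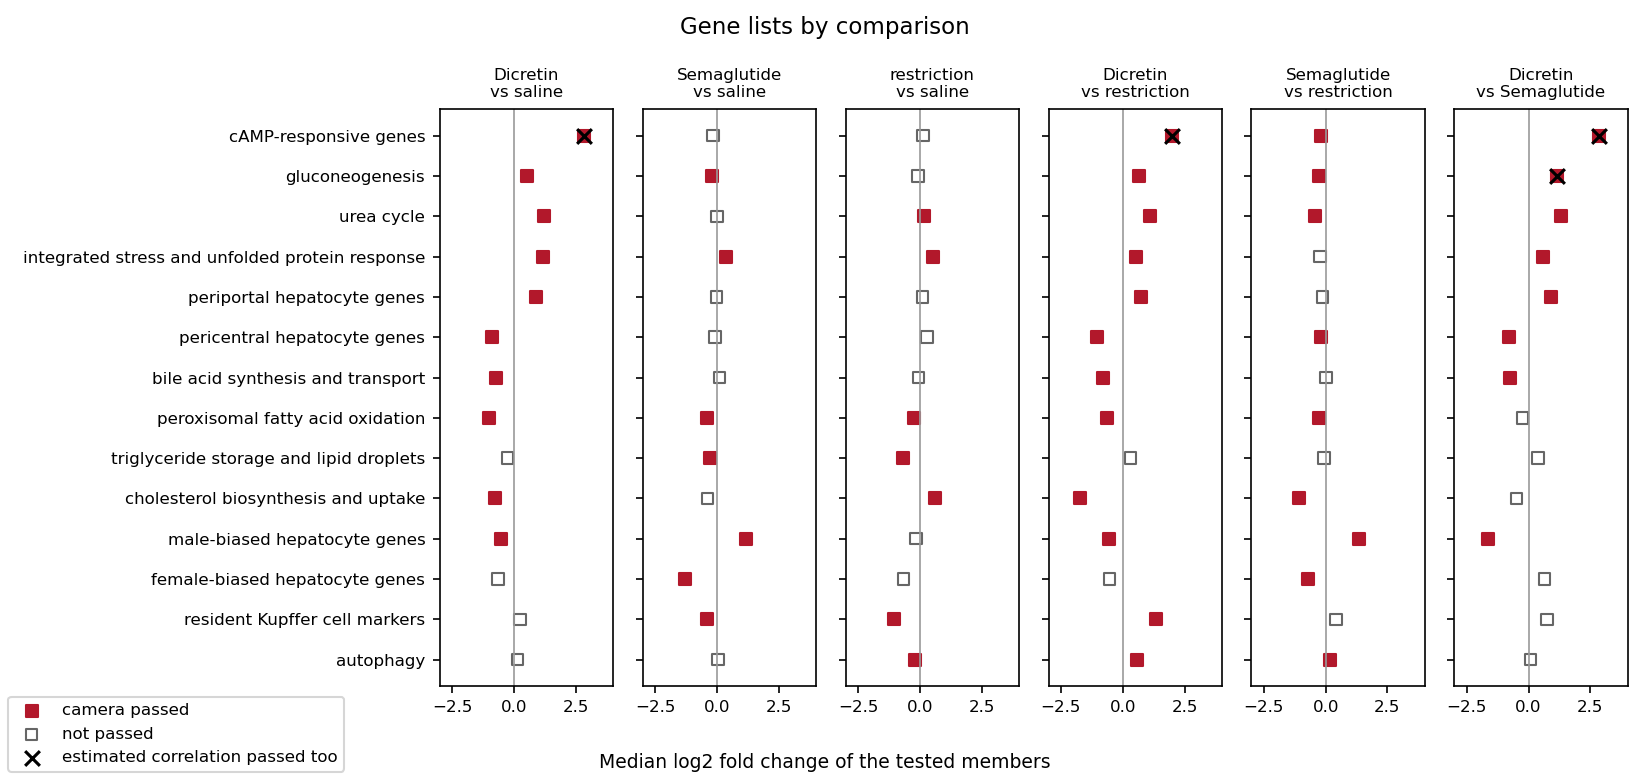
Median log2 fold change of 14 gene lists in each of the 6 comparisons, with filled squares where camera with the preset correlation passed the adjusted p threshold of 0.05 and crosses where the estimated correlation passed as well. The cyclic AMP list has medians of 2.83 and 2.86 for Dicretin against saline and against Semaglutide and -0.17 between Semaglutide and calorie restriction.

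Calls shared between comparisons measured how far the treatments moved the same genes. Dicretin and calorie restriction shared 572 calls in the same direction against saline, 238 higher and 334 lower, and 64 calls went opposite ways. Independent lists of these sizes would share 77.2 and 101.8. When all groups were simulated as unchanged, with the simulated saline libraries used in both comparisons, 0.05 calls were shared on average. Such data give almost no calls, so this value cannot show how far a shared saline group raises the overlap. Dicretin and Semaglutide shared 312 (92 higher, 220 lower, 62 opposite, with 35.11 and 64.9 from independent lists and 0.05 from unchanged groups), and Semaglutide and calorie restriction shared 218 (55 higher, 163 lower, 16 opposite, with 6.882 and 13.88 from independent lists and 0.05 from unchanged groups). With the saline libraries split so that each comparison had its own, the counts were 55 and 117 for Dicretin and restriction, 13 and 81 for Dicretin and Semaglutide, and 4.5 and 45.5 for Semaglutide and restriction, higher and lower, where independent lists would share 12.77 and 25.62, 3.632 and 17.82, and 0.2888 and 1.731. Without Semaglutide 11 and Dicretin 14 the shared counts rose to 977 for Dicretin and restriction and to 342 for Semaglutide and restriction, and DESeq2 gave 527 for Dicretin and Semaglutide and 356 for Semaglutide and restriction. The covariances of log2 fold changes across genes were 0.243, 0.193 and 0.169, against 0.05, 0.049 and 0.05 in the simulation, which left differences of 0.193, 0.144 and 0.119. The correlations were 0.409, 0.343 and 0.521, against 0.499, 0.494 and 0.501 in the simulation, where shared saline libraries alone correlate the comparisons. With the saline libraries split, so that none was shared, they were 0.316, 0.259 and 0.358. Cidea, Cidec, Pparg and Cfd fell in all 3 comparisons with saline. Dicretin against saline and against calorie restriction shared 2871 calls, 1337 higher and 1534 lower with 19 opposite (340.8 and 401.3 from independent lists, 0 from unchanged groups, and 808.5 and 917.5 with the Dicretin libraries split, where independent lists would share 179.5 and 212.9), and the covariance of 0.788 exceeded the simulated 0.05 by 0.737, with a correlation of 0.824 against 0.502 in the simulation and 0.694 with the split. Ppargc1a, Crem, Nr4a1, Lepr and Wnt10a were higher in both.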

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

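In each group of 4 libraries, a gene printed in the text was examined when its mean was at least 1 CPM, by dividing the gap between the highest or lowest library and its nearest mate by the range of the group. A library lay far from its mates in 28 of 375 groups, and chance puts about 1 in 20 groups past the limit. The values below are CPM of the library against the range of its mates, followed by the ratio of gap to range, and no explanation was tested for any of them.

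Calorie-restricted library 79 was the highest of its group for Atf5 (474.9 against 221.1 to 240.8, 0.922), Fgf21 (5.945 against 1.256 to 1.81, 0.882), Gdf15 (7.682 against 1.833 to 2.278, 0.924), Hmgcs1 (783.9 against 193.3 to 218.1, 0.958) and Igfbp1 (57.05 against 21.78 to 26.48, 0.867). It was also the highest for Lipe (8.15 against 7.125 to 7.256, 0.872), Pitx3 (6.947 against 1.375 to 2.219, 0.849) and Srebf2 (73.01 against 40.17 to 42.4, 0.932). Saline library 78 was the highest of its group for Clec2h (16.79 against 4.159 to 5.92, 0.861) and Map1lc3b (145.7 against 122 to 124.3, 0.905), and the lowest for Cyp8b1 (168.8 against 396.8 to 434, 0.86). Semaglutide library 11 was the highest of its group for Enho (58.35 against 32.18 to 34.67, 0.905) and Nnmt (137.7 against 52.47 to 62.54, 0.882), and the lowest for Lipe (7.425 against 14.4 to 15.81, 0.832). Dicretin library 14 was the highest of its group for Fasn (522.7 against 14.72 to 41.59, 0.947), Pappa2 (13.87 against 2.599 to 4.268, 0.852) and Scd1 (7615 against 169.3 to 1391, 0.836). Semaglutide library 51 was the highest of its group for Got1 (239 against 126.1 to 132.8, 0.94), Hyou1 (151.9 against 69.17 to 73.61, 0.946) and Lepr (23.41 against 8.7 to 9.803, 0.925). Semaglutide library 15 was the highest of its group for Cyp1a2 (618.5 against 435.7 to 464, 0.846) and Lmod2 (9.665 against 0.313 to 1.296, 0.895). Calorie-restricted library 8 was the highest of its group for Mup17 (54.38 against 6.657 to 13.56, 0.855) and Nnmt (188 against 93.52 to 107.4, 0.854). Dicretin library 64 was the highest of its group for Asns (25.75 against 17.73 to 18.88, 0.857). Semaglutide library 31 was the lowest for Dnajb11 (77.18 against 97.96 to 101.8, 0.845). Dicretin library 65 was the highest of its group for Hspa5 (1652 against 795.8 to 934.5, 0.838). Saline library 50 was the highest of its group for Mup18 (64.78 against 2.248 to 8.023, 0.908).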

How the results depend on the processing

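The length correction and the joint removal of Semaglutide 11 and Dicretin 14 were chosen after the data had been seen, and every other alternative was planned. Of 175 results for named genes, 163 kept their direction and their side of the threshold under every alternative run for them, and 12 did not. Many of these genes were named for large changes or small p, and examples were chosen with leave-one-out values in view. This share therefore does not stand for genes in general. With DESeq2 size factors, upper quartile factors, the DESeq2 test or the length correction, all 175 did so, and 171 did without the count filter. Under the filter of 1 CPM 172 could be tested, and 171 with the 20 most abundant genes left out. Of 68 list results, 53 kept theirs under all alternatives except the estimated correlation, under which 59 calls were lost. No scaling moved the median of all genes by more than 0.1 on the log2 scale.

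DESeq2 called 943 genes for Semaglutide against saline, 1465 for calorie restriction against saline and 1266 for Semaglutide against calorie restriction, with 527 shared by Dicretin and Semaglutide and 356 by Semaglutide and restriction against saline. With only the groups compared, the calls were 2569 for restriction against saline and 2658 for Dicretin against Semaglutide. The estimated correlation left 1 list for Dicretin against saline, 0 for Semaglutide against saline, 0 for restriction against saline, 1 for Dicretin against restriction, 0 for Semaglutide against restriction and 2 for Dicretin against Semaglutide. The camera test with the preset correlation called 19, 15 and 14 lists where these counts are 0. Fry called 11 lists for Semaglutide against saline, 9 for restriction against saline and 8 for Semaglutide against restriction.

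Without Semaglutide 11 and Dicretin 14, 1880 genes were called for restriction against saline and 17 lists for Dicretin against Semaglutide. Shared calls were then 977 for Dicretin and restriction and 342 for Semaglutide and restriction, oxidative phosphorylation reversed in Semaglutide against saline (adjusted p = 0.724), and Cyp8b1 reversed in Dicretin against Semaglutide (log2 fold change 0.095). With the shared group divided between the comparisons, shared calls were 172 for Dicretin and restriction, 94 for Dicretin and Semaglutide, 50 for Semaglutide and restriction, and 1726 for Dicretin against saline and against restriction. Fewer libraries then entered each comparison and none was shared, and the parts of these changes were not separated.

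With 1 library left out at a time, the calls ranged from 256 to 512 for Semaglutide against saline, 502 to 849 for restriction against saline and 445 to 963 for Semaglutide against restriction, and from 9 to 16 lists for restriction against saline. The adjusted p of oxidative phosphorylation in Semaglutide against saline ranged from 4.33e-05 to 0.76, the log2 fold change of Cyp8b1 in Dicretin against Semaglutide from -0.572 to 0.214, and that of Pck1 in Semaglutide against saline from -0.38 to 0.032. Neither gene passed in these comparisons. The cause of these shifts was not tested. No paired analysis was possible because the groups share no animal number. At 12.144 M counts in the smallest library, genes near the floor of 3 counts over a group are measured coarsely, and a fold against a group without counts is only a lower bound.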

Other observations

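The tests of the clock genes, the test of other cell types' markers, the correction for gene length and the joint removal of Semaglutide 11 and Dicretin 14 were chosen after the results were seen, as were Mylpf and Des among the genes named here. A list of adipocyte marker genes, several of which also stand in the lipid lists, was lower than in saline in all 3 treated groups. With Dicretin, 1 rose and 5 fell of 7 tested members (1 and 5 adjusted over the list alone) (camera adjusted p = 0.022, adjusted p = 0.226 with an estimated correlation), with Semaglutide 0 rose and 3 fell of 7 tested members (1 and 4 adjusted over the list alone) (camera adjusted p = 0.00091, adjusted p = 0.0878 with an estimated correlation), and with calorie restriction 3 of 7 tested members fell (3 adjusted over the list alone) (camera adjusted p = 0.000216, adjusted p = 0.0791 with an estimated correlation). The hormone-sensitive lipase gene Lipe had log2 fold changes of -1.60 ± 0.20, -1.09 ± 0.20 and -1.92 ± 0.20 in that order. It was at 7.425 CPM in Semaglutide library 11 and at 14.4 to 15.81 CPM in its mates, and without that library its log2 fold change was -0.90 (adjusted p = 0.00389).

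In Dicretin livers, 6 of 29 tested members fell (5 adjusted over the list alone) of the stellate cell and extracellular matrix list (camera adjusted p = 0.0129, adjusted p = 0.69 with an estimated correlation), a call lost without Dicretin library 64 (adjusted p = 0.0556). The collagen Col3a1 fell from 37.2 ± 17.2 to 13 ± 7.2 CPM and the proteoglycan Bgn from 101 ± 25.4 to 59.5 ± 14.5 CPM (largest adjusted p 0.01). In de novo lipogenesis, Semaglutide livers were lower than calorie-restricted ones, where 2 of 22 tested members fell (5 adjusted over the list alone) (camera adjusted p = 0.000733, adjusted p = 0.637 with an estimated correlation), although fry did not call the list (adjusted p = 0.14).

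Oxidative phosphorylation genes were higher in Dicretin than in saline, and 11 of 39 tested members rose (7 adjusted over the list alone) (camera adjusted p = 0.00235, adjusted p = 0.764 with an estimated correlation), while fry did not call the list (adjusted p = 0.182). Uqcrh of complex III rose by 1.03 ± 0.29. The tables argue against gene length as the cause, since the list's median was 0.37 before and 0.38 after the length trend of each library was removed, and the members called higher went from 11 to 19. After that correction the list mean of 4 of 4 Dicretin libraries lay above every saline library, at 7.71 to 8.03 against 7.39 to 7.58 log2 CPM, so the treatment may raise these genes in each animal. Before the correction Dicretin 14, at 7.48, lay below some saline libraries.

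Clock genes differed in both directions between calorie-restricted and saline livers, and 5 rose and 5 fell of 19 tested. In arms drawn after these changes were seen, the Arntl arm (4 tested genes) had a median log2 fold change of 2.01 and the Dbp arm (8 tested genes) one of -1.65, a difference of 3.664, although Hlf of the Dbp arm, at 0.30 ± 0.18, did not pass. Dicretin livers showed 1.85 and -1.09, and Semaglutide livers -0.26 and 0.34. The tables argue against gene length, since 10 of the 10 called clock genes stayed called in the same direction after its trend was removed. A shift of the clock phase through feeding or sampling time stays open, because the arms were drawn from the changes they would test and neither time was given in the sources used here.

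The lower pericentral and higher periportal levels in Dicretin livers could come from less pericentral tissue in the samples or from fewer hepatocytes. The 7 markers of the hepatocytes that hold Glul had a median of -0.528, against -0.89 for the pericentral list and -1.53 for its other members, which lay between the bounds set for this test, so less pericentral tissue and lower expression cannot be told apart. These markers went both ways, with Glul at -2.24 ± 0.21, while Axin2 at 0.34 ± 0.29 and Oat at 0.53 ± 0.24 did not pass, though Oat was higher without Dicretin 14 (adjusted p = 0.0284). Fewer hepatocytes, with the other cells unchanged, would raise the markers of all those cells alike. The medians of 4 such lists lay 1.338 apart, at 0.25 for Kupffer cells, 0.03 for sinusoidal endothelium, -0.77 for stellate cells and -1.09 for cholangiocytes. These values argue against that case only. Fewer hepatocytes together with changes in the other cells stay open, because cell numbers were not measured. A direct effect of the co-agonist on these genes was not tested separately.

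For each comparison, the 8 libraries were split into groups of 4 in all 35 ways. The real split alone (1 of 35) gave as many calls in every comparison. A share of 1 in 35 is the smallest this test can give, so it cannot exclude chance. The other splits mix libraries of the compared groups, so their counts do not show what unchanged groups would give. The comparisons also share libraries and are not separate tests. The real and the highest other counts were 4734 and 2 for Dicretin against saline, 539 and 2 for Semaglutide against saline, 972 and 0 for calorie restriction against saline, 4041 and 4 for Dicretin against calorie restriction, 790 and 1 for Semaglutide against calorie restriction, and 4128 and 1572 for Dicretin against Semaglutide. The split with 1572 exchanged Semaglutide 11 with Dicretin 14. The next, with 621, put Semaglutide 11 and 31 with Dicretin 64 and 65. It too parts 11 from 14, so it cannot show a structure beyond them.

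Semaglutide 11 lay farther from its group than any mate, at 1.36 times the distance of the farthest mate and 1.26 times after the length trend was removed (distances of 0.691 and 0.508 before, 0.614 and 0.489 after). What sets this library apart was not decided by these values. Its shortest genes exceeded its longest by 0.73 on the log2 scale, against -0.49 in Dicretin 14, 0.34 in Dicretin 65, 0.29 in Dicretin 64 and -0.3 to 0.11 in the other libraries. The mean of the oxidative phosphorylation list was 8.37 in Semaglutide 11 and 7.34 to 7.65 in its mates, and that of the cholangiocyte list 1.91 and 0.92 to 1.05 log2 CPM. In Semaglutide against saline, removing the length trend took the median of the oxidative phosphorylation list from 0.235 to 0.117, and the list still passed (adjusted p = 0.0402). Dicretin 14 had means of 3.1 for cell cycle genes and 6.78 for de novo lipogenesis, against 1.19 to 1.43 and 5.22 to 5.83 in its mates. The muscle genes Mylpf and Des stood at 45.6 and 61 CPM in Semaglutide 15, against 0.376 to 0.975 and 4.57 to 6.15 CPM in the other Semaglutide libraries.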
